A study of Mus musculus with 38 samples.

How the data were processed

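Messenger RNA was measured in Neuro2A cells, a mouse neuroblastoma line used as a model of neuronal differentiation, before and after exposure to all-trans-retinoic acid, the ligand of the retinoic acid receptors. Per the labels' protocols, cells were precultured for 48 h in medium with 10% fetal bovine serum. The control arrays (0 h) held RNA taken at that point. For the treated arrays the medium was replaced by medium with 2% serum and 20 uM retinoic acid, and RNA was taken 1, 3, 6, 12 or 24 h later. Each replicate pooled 4 to 6 plates. Labels name no vehicle control and no control for the change of medium, so every comparison against 0 h holds retinoic acid, the lower serum and the time in culture together. Within the treated arrays every array had the change of medium, but early and late arrays differ in the time since it, so late minus early can hold a fading or delayed response to it.

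Polyadenylated RNA was labelled with Cy5, hybridised to oligonucleotide arrays of mouse KIAA genes (a collection of long, mostly brain-derived cDNAs), scanned on an FLA-8000 imager and quantified with Phoretix software, per the labels' protocols. Each sample was a single-colour hybridisation. The label text breaks off at the quantification step. How the authors corrected background, scaled the arrays and set a floor is not given in the sources used here. The deposited values were linear Cy5 intensity values for 576 probes on 38 arrays, with no missing value. On every array between 54.5% and 55.0% of probes lay below 1, which shows a scaling to a fixed rank, and 30 arrays shared a lowest value of 0.540, referred to as the floor. The other 8 arrays never reached it. No value for spot background or detection was used here, so the floor was the only sign of a probe without signal, and a probe at the floor has only an upper limit.

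Probes were named from the platform annotation supplied with the series. There were 473 probes with exactly 1 gene, none with several and 103 unnamed here. Gene identifiers were looked up in a RefSeq gene table (assembly GRCm38.p6): 472 were found, 1 was not, and 0 symbols changed. No genome build is named for the array, so no coordinates are given. Of the unnamed probes, 76 lay at the floor on over 50% of arrays, against 23 of the named probes. Each named gene was represented by its own probe, and an unnamed probe is referred to by its number.

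The design and its tests were fixed before the data were examined. Deposited values were taken to log2. Because the array medians differed by 0.23 on the log2 scale, over the limit of 0.1 set in advance, arrays were quantile normalised. All 576 probes were fitted with limma (version 3.58.1 in R 4.3.3) on all 38 arrays, with the 6 groups as the only factor, leaving 32 residual degrees of freedom shared over groups. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all probes of a contrast, with a threshold of 0.05. The contrasts were each of the 5 times against 0 h, neighbouring times, late minus early (the mean of 12 and 24 h minus the mean of 1 and 3 h), and a moderated F test over the 5 times against 0 h. Standard errors (SE) are those of the moderated fit. All fold changes are on the scale of normalised intensity.

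A set of 13 gene lists, with 871 symbols from textbook functions of KIAA-type genes and markers of other cell types, was also fixed in advance. The array measured 198 of these symbols. Lists with at least 4 measured genes (12 of the 13) were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, in 6 contrasts each, and the 72 tests were adjusted together. Named genes followed a rule set in advance: at 24 h the 12 largest rises and the 12 largest falls past the threshold with at least 6 of 7 treated arrays on that side of the control mean; in other contrasts the 5 largest on each side past the threshold; and of every list the 4 members with the smallest p at 24 h, whether or not they passed. Similarity of the time points was the Pearson correlation across probes of their log2 fold changes against 0 h, set beside 1000 simulated sets of unchanged groups that share the control arrays and beside 35 divisions of the controls into sets of 4 and 3.

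Before use, the tests were run on simulated data made from the residuals of the real arrays, on all 576 probes, with 30 probes changed by each fold size in each of 20 simulations. For 24 h against 0 h, 47.5% of probes changed by 1.5-fold and 79.3% of those changed by 2-fold were called, and 4.16% of calls were false. For late minus early, 67.8% and 96.3% were called, and 1.60% of calls were false. In simulations with no change, 20 calls arose over 20 simulations of 10 contrasts, and no list passed. A list shifted by 0.5 on the log2 scale at 24 h passed in 20 of 20 simulations on the 473 named probes. That shift was the same for all members and larger than any list median in the real data. The largest of those was -0.21, for ubiquitin ligases and deubiquitinases at 6 h. How often smaller shifts would pass was not simulated. The simulations shuffled arrays over the times, so these rates do not hold the link between array range and time in the real data. Changed probes were drawn from all 576, those at the floor included, and no floor was set, so real rates can differ.

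Alternatives fixed in advance were no further normalization, median centring, leaving out the dimmest 25% of probes, adding the 5th percentile of all values before log2, the replicate number as a fixed or random block, array quality weights, only the arrays compared, an intensity trend with robust variances (statmod 1.5.0), a fold minimum of 1.5, and leaving out each array in turn. Added after the data were examined were fits without the 8 arrays that did not reach the floor, without 5 arrays whose median rank correlation with the others was under 0.7, with the interquartile range of each array as a covariate, after a correction for position on the array (runs of 24 consecutive probe numbers and the remainder modulo 12), and with quality weights after that correction. Figures were drawn with matplotlib 3.10.9. No 2 arrays among the 703 pairs held identical values. The labels call the arrays replicates and do not say whether they came from separate cultures, so p-values measure only the spread between these arrays, which may be partly technical.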

Results

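The time course covered 38 single-colour arrays of Neuro2A cells: 7 controls at 0 h, 5 arrays at 1 h, 5 at 3 h, and 7 each at 6, 12 and 24 h of 20 uM retinoic acid. Its title names the question as differentiation of a neuroblastoma line under retinoic acid. The array holds 473 probes with a named gene and does not cover the whole transcriptome; 198 of its genes belong to the lists fixed in advance, which cover the cytoskeleton, the synapse, chromatin and signalling among others. The number of arrays limits the precision: the median SE of a log2 fold change was 0.18 for 6, 12 or 24 h against 0 h, a factor of 1.14, and 0.20 for 1 or 3 h. Rank correlations between arrays of 1 group (median 0.797) were no higher than between arrays of different groups (median 0.801), so differences between groups were small beside differences between arrays.

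The arrays differed in range along the time course. The interquartile range of the deposited log2 values was 1.51 ± 0.22 (SD, n = 7) in the controls, 1.56 ± 0.14 (n = 5) at 1 h, 1.64 ± 0.09 (n = 5) at 3 h, 1.14 ± 0.41 (n = 7) at 6 h, 1.13 ± 0.54 (n = 7) at 12 h and 0.88 ± 0.16 (n = 7) at 24 h. The 24 h arrays lay below the controls without overlap (two-sided exact permutation test over 3432 splits, p = 0.000583). Of the 8 arrays that never reached the floor, 2 were at 6 h, 2 at 12 h and 4 at 24 h.

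**Figure D1:**
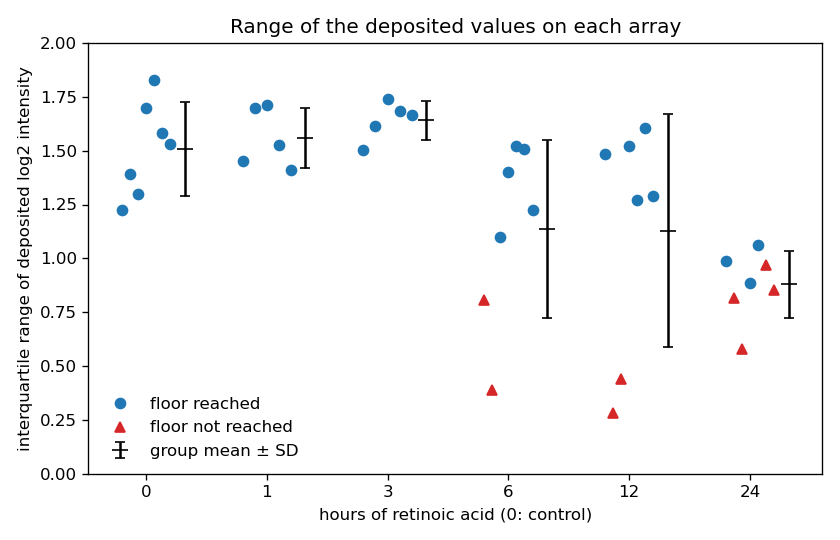
Interquartile range of the deposited log2 intensities of each array (vertical axis, log2 units) by hours of retinoic acid, with 0 for the control. Circles are arrays that reach the floor, triangles arrays that do not, and bars the group mean ± SD; the 24 h arrays, with a mean of 0.88, all lie below the controls, with a mean of 1.51.

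After 24 h, 6 of 576 probes differed from the control, 4 higher and 2 lower. Plekhg1 rose 1.86-fold, from a normalised log2 intensity of -0.40 ± 0.27 (SD, n = 7) to 0.49 ± 0.24 (n = 7); its log2 fold change was 0.90 ± 0.15 (SE, limma adjusted p = 0.000801). Cyfip2, a subunit of the WAVE complex that directs actin polymerisation, rose 2.00-fold (log2 1.00 ± 0.20, adjusted p = 0.00485), from -0.07 ± 0.37 to 0.93 ± 0.53. Atmin, a zinc-finger protein named for its interaction with the ATM kinase, rose 1.77-fold (log2 0.82 ± 0.20, adjusted p = 0.0296). Ablim1, an actin-binding LIM protein, fell by 0.89 on the log2 scale (SE 0.20, adjusted p = 0.00968), from 0.73 ± 0.23 to -0.17 ± 0.46, and Mark3, a kinase of microtubule-associated proteins, fell by 0.67 (SE 0.16, adjusted p = 0.0241), from 1.03 ± 0.31 to 0.36 ± 0.40. Each of these 5 genes lay on the same side of the control mean in 7 of 7 arrays at 24 h. Plekhg1 lay at the floor on 1 control array and Ablim1 on 1 array at 24 h, so their sizes rest in part on values with only an upper limit.

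The remaining probe called at 24 h, unnamed probe 439, was 3.00-fold higher (log2 1.59 ± 0.31, limma adjusted p = 0.00392) and above the control mean in 7 of 7 arrays. On 24 h replicate 3 it was at 3.63, the same value as on control replicates 1, 2, 3, 5 and 6, where the control mean was 3.26. It was among the brightest spots, with a median place of 6 from the top in the controls and 3 at 24 h, and after quantile normalization it took only 7 distinct values over the 38 arrays. On the values as deposited its log2 change was 1.03 with an adjusted p of 0.0946.

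**Figure D2:**
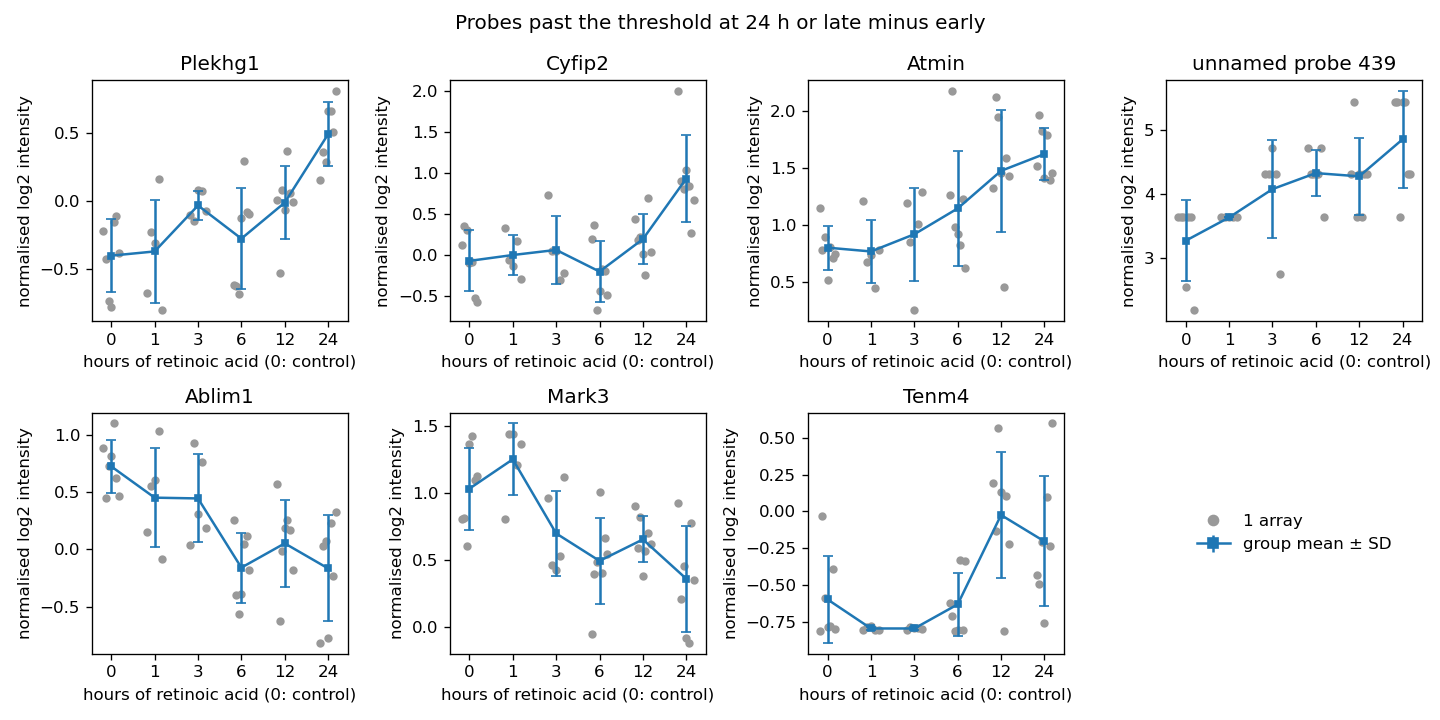
Normalised log2 intensity (vertical axes) by hours of retinoic acid (0 is the control) for the 7 probes past the threshold at 24 h or late minus early. Grey points are arrays and blue squares with bars are group means ± SD; Plekhg1 goes from -0.40 to 0.49 and Ablim1 from 0.73 to -0.17 between 0 and 24 h.

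Calls at 24 h depended on how the range of the arrays was handled. With no normalization after deposit, 11 probes passed, 3 higher and 8 lower, and with median centring 12, 3 higher and 9 lower. Of the 6 probes, 4 were among either set (Plekhg1, Cyfip2, Ablim1 and Mark3), while the log2 change of Atmin was 0.35 (adjusted p = 0.243) and 0.28 (adjusted p = 0.408). With the array range as a covariate 2 probes passed, Plekhg1 being the only one shared with the 6. Leaving out single arrays ended the call of Atmin for 8 arrays and of Mark3 for 7 of the 38, and leaving out control replicate 1 raised the count to 10.

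At 6 h, Ablim1 was lower than the control by the amount seen at 24 h: it fell by 0.88 (SE 0.20, limma adjusted p = 0.0429), to -0.16 ± 0.31 (SD, n = 7). It was the only probe called at 6 h, and 20 of the 38 arrays ended the call when left out, with the log2 change between -0.81 and -0.96. Over 14 other settings the call held in 10 and ended in 4. Among the 4 were trend and robust variances (limma adjusted p = 0.0513), leaving out the 5 arrays of low correlation (0.0585) and the range covariate (log2 -0.74, 0.158). At 1, 3 and 12 h no probe passed in limma; 8, 31 and 23 probes had an unadjusted p under 0.05, where 28.8 would have by chance, against 33 at 6 h and 39 at 24 h. The log2 values of Ablim1 against 0 h were -0.27 at 1 h, -0.28 at 3 h and -0.67 at 12 h. Those of Plekhg1 were 0.03, 0.37, 0.13 and 0.39 at 1, 3, 6 and 12 h, and those of Cyfip2 0.07, 0.13, -0.13 and 0.26.

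Steps between neighbouring times asked when in the course a change came. None of the 4 steps gave a call in limma: 21 probes from 1 to 3 h, 23 from 3 to 6 h, 24 from 6 to 12 h and 22 from 12 to 24 h had an unadjusted p under 0.05. The last step was 0.50 for Plekhg1 (adjusted p = 0.435) and 0.74 for Cyfip2 (adjusted p = 0.296) on the log2 scale. With array quality weights, 21 probes passed from 1 to 3 h and 1 from 6 to 12 h.

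Within the treated arrays, 2 genes were higher late (12 and 24 h) than early (1 and 3 h), and none was lower. Tenm4, a teneurin, a transmembrane protein of neuronal adhesion, rose by a fitted 1.60-fold (log2 0.68 ± 0.13 SE, limma adjusted p = 0.00357), a size that rests on values at the floor and was 0.40 on the log2 scale with an offset added. It lay at the floor on all 10 early arrays, on 3 of 7 arrays at 6 h and on 1 of the 14 late arrays, but only 5 of the 7 arrays at 6 h and 8 of the 14 late arrays reached the floor at all. Without the 8 arrays that did not, the log2 change of Tenm4 was 0.61 (adjusted p = 0.0460). On the control arrays it lay at the floor on 4 of 7, and 24 h against 0 h did not pass (log2 0.39 ± 0.16, adjusted p = 0.490). Atmin rose 1.63-fold (log2 0.71 ± 0.16, adjusted p = 0.0253), with group means of 0.77 at 1 h, 0.92 at 3 h, 1.14 at 6 h, 1.47 at 12 h and 1.62 at 24 h. An unadjusted p under 0.05 was found for 78 probes, against 28.8 by chance. This count was the one that moved most with processing: 78 probes passed on the values as deposited (42 higher, 36 lower), 65 after median centring (18 higher, 47 lower) and 166 with array quality weights (58 higher, 108 lower), of which 62 lay at the floor on over 50% of arrays. Leaving out 24 h replicate 1 gave 12. Tenm4 passed on the values as deposited and Atmin did not. Its log2 change was 0.25 as deposited (adjusted p = 0.198), 0.18 with median centring (adjusted p = 0.403) and 0.27 with the range covariate (adjusted p = 0.474). Atmin also lost this call with only the arrays compared (0.69) and without the 8 arrays above the floor (0.61).

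Over the whole course, 6 probes passed the moderated F test: Plekhg1 (adjusted p = 0.00803), Cyfip2 and Mark3 (both 0.0174), Ablim1 and Tenm4 (both 0.0216) and unnamed probe 439 (0.0353). Atmin had an adjusted p of 0.0551. The count moved with processing, from 2 with the array range as a covariate to 81 with weights after the position correction, and was 17 on the values as deposited. No probe passed from 0 h to the early arrays (19 had an unadjusted p under 0.05), so no transient or continued course could be called, and 0 would be expected from independent lists; Tenm4 and Atmin were late only.

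Genes of the actin cytoskeleton went both ways. Among 16 measured genes of the actin cytoskeleton, 1 rose at 24 h (Cyfip2) and 1 fell (Ablim1), and the same number, 2, passed when adjusted over the list alone; the talin Tln2, which links integrins to actin, was at -0.45 ± 0.18 (log2 ± SE) and Plekhh1 at 0.51 ± 0.27. As a list the genes did not shift (9 higher, 7 lower, camera adjusted p = 0.949). Of 20 genes of microtubules and kinesins none passed at 24 h, over all probes or adjusted over the list alone. Cep170b, a centrosomal protein, was at 0.59 ± 0.25, the dynein heavy chain Dync1h1 at 0.48 ± 0.24, the minus-end protein Camsap2 at -0.43 ± 0.26 and the kinesin Kif17 at 0.10 ± 0.07. Dync1h1 took the opposite sign on the values as deposited (-0.16). The list's median was -0.0025 with a mean of 0.04, and its test leaned up (adjusted p = 0.949).

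Neuronal surface and synaptic genes did not pass at 24 h. Of 20 genes of axon guidance and adhesion 13 were higher and 7 lower (camera adjusted p = 0.759). The teneurins took opposite signs, with Tenm4 at 0.39 ± 0.16 and Tenm3 at -0.50 ± 0.23; the semaphorin receptor Plxna2 was at 0.63 ± 0.30 and the adhesion protein Kirrel3 at 0.26 ± 0.14. Of 25 synaptic genes 17 were higher and 8 lower (adjusted p = 0.543), with Stxbp5, a tomosyn that binds SNARE proteins, at 0.27 ± 0.16, Psd3 at 0.22 ± 0.14, Tspoap1 at 0.07 ± 0.05 and the synaptotagmin Syt11 at 0.28 ± 0.19; Syt11 was at -0.14 on the values as deposited. No member of either list passed at 24 h in the fit described, over all probes or adjusted over the list alone. Psd3 passed without the 8 arrays above the floor (log2 0.69, adjusted p = 0.00788), and was at -0.053 with weights after the position correction (adjusted p = 0.822). With no normalization after deposit the axon guidance list passed upward in camera at 24 h (adjusted p = 0.0116), and with median centring both lists did (adjusted p = 0.00840 and 0.0498). Neither scaling removes the narrower range of the 24 h arrays. As deposited, brighter probes went lower from early to late times (correlation -0.658 with the mean level). Whether the level of a list's members enters these calls was not tested.

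Members of the lists of transcription factors, cell cycle and chromatin gave no call at 24 h over all probes. Tle3, a Groucho-family co-repressor, was at 0.94 ± 0.27 (adjusted p = 0.0988) and St18, a zinc-finger factor related to Myt1, at -0.31 ± 0.09 (adjusted p = 0.127); both of these, out of 18 transcription factors, passed when adjusted over the list alone, and Camta2 was at -0.38 ± 0.17 and Myt1 at 0.36 ± 0.19. Tle3 passed over all probes when dim probes were left out (adjusted p = 0.0432) and without the 8 arrays above the floor (log2 1.62, adjusted p = 0.00124). It was at 0.38 (adjusted p = 0.395) on the values as deposited and 0.32 (adjusted p = 0.550) with median centring, within a range of adjusted p from 0.00124 to 0.554 over 14 settings. Of 4 genes of the cell cycle, the cohesin regulator Pds5b was at -0.47 ± 0.15 (adjusted p = 0.161) and passed when adjusted over the list alone and, over all probes, on the values as deposited (adjusted p = 0.0230). Cdk19 was at 0.29 ± 0.24, Smc5 at 0.20 ± 0.28 and Mcm3ap at 0.11 ± 0.18, the last with a value of -0.077 as deposited; the list's median (0.16) and mean (0.03) were above 0 while its test leaned down (adjusted p = 0.949). Of 16 chromatin genes 7 were higher and 9 lower at 24 h (adjusted p = 0.759), with the histone methyltransferase Kmt2b at -0.43 ± 0.18, the Polycomb subunit Suz12 at -0.66 ± 0.39, the remodeller Chd6 at -0.27 ± 0.17 and the demethylase Phf8 at 0.39 ± 0.25.

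Genes tied to retinoic acid signalling were few on the array. Of 40 fixed symbols 5 were measured, none of which passed at 24 h, and 1 was higher and 4 lower (adjusted p = 0.759). Zfp423, a zinc-finger partner of the retinoic acid receptor, was at -0.28 ± 0.18, the co-regulator Rere at 0.30 ± 0.23, Acin1 at -0.20 ± 0.20 and the Mediator subunit Med13l at -0.16 ± 0.24; Rere was at -0.0050 after median centring. At 1 h the list had a median log2 change of 0.20 (limma camera, adjusted p = 0.352).

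Genes of protein turnover, RNA processing and autophagy did not pass. Of 22 ubiquitin ligases, deubiquitinases and adaptors 15 were lower and 7 higher at 1 h, with a median of -0.20, and this was the smallest p of the 72 list tests (camera p = 0.000739, adjusted p = 0.0532); with an estimated correlation the adjusted p was 0.235. On the values as deposited the list passed downward in camera at 1, 6, 12 and 24 h (adjusted p = 0.00807, 0.00458, 0.00624 and 0.00554). Those values keep the narrower mean range of the arrays at 6, 12 and 24 h, and whether it enters the calls at these times was not tested. At 1 h the list also passed in camera with median centring (adjusted p = 0.00727), after the position correction (0.00728) and without the 8 arrays above the floor (0.0465). Leaving out any of 10 of the 38 arrays gave this call as well. At 24 h 8 members were higher and 14 lower, none passed, and the deubiquitinases Usp31 and Usp33 were at -0.43 ± 0.17 and -0.32 ± 0.24, and the ubiquitin ligase adaptors Dcaf1 and Dcaf5 at -0.52 ± 0.25 and 0.39 ± 0.16; Dcaf5 was at -0.00082 after median centring. Of 12 genes of RNA processing and ribosome biogenesis 9 were lower at 24 h and 3 higher, with a median of -0.19 (limma camera, adjusted p = 0.446, and adjusted p = 0.705 with an estimated correlation). Rrp12 was at -0.32 ± 0.18, the RNA-binding protein Pum2 at -0.50 ± 0.29, the export receptor Xpo7 at -0.38 ± 0.25 and the splicing factor Srrm2 at -0.37 ± 0.27. Of 18 genes of autophagy and endolysosomal trafficking 14 were higher and 4 lower (adjusted p = 0.742), with Vps13b at 0.16 ± 0.11, the kinase Ulk2 at 0.21 ± 0.16, Epg5 at 0.20 ± 0.18 and the phosphatase Mtmr3 at 0.16 ± 0.16. None of these passed over all probes or adjusted over the list alone in the fit described. Usp31 passed over all probes on the values as deposited (log2 -0.75, adjusted p = 0.0102), with median centring (-0.81, adjusted p = 0.00839), after the position correction (-0.55, adjusted p = 0.0128) and with weights after it (-0.60, adjusted p = 0.000501), within a range of adjusted p from 0.000501 to 0.554 over 14 settings.

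Only 2 of the 52 fixed markers of matrix, stromal and glial cells were measured, too few for a test: Pxdn, a peroxidase of the extracellular matrix, was at -0.27 ± 0.23 and Phldb1 at -0.20 ± 0.18 at 24 h. The members of 1 of the 13 lists are not described. With weights after the position correction, members named above that did not pass in the fit described passed over all probes at 24 h: Cep170b, Dync1h1, Camsap2, Tln2, Plekhh1, Tenm4, Tenm3, Tle3, St18, Myt1, Kmt2b, Suz12, Usp31, Usp33 and Xpo7. In all, 0 of the 72 list tests of limma's camera passed and 8 had an unadjusted p under 0.05. In the simulations with no change, 7.08% of list tests had a camera p under 0.05 at the preset correlation. With the correlation estimated the share was 3.54%. For late minus early, Tenm4 was the 1 member of the axon guidance list that rose, and 1 passed adjusted over the list alone; so did 4 actin genes and 2 genes of the retinoic acid list, none of which passed over all probes. Of 16 chromatin genes 12 were lower late than early, with a median of -0.21 (adjusted p = 0.390, and 0.485 with an estimated correlation).

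**Figure D3:**
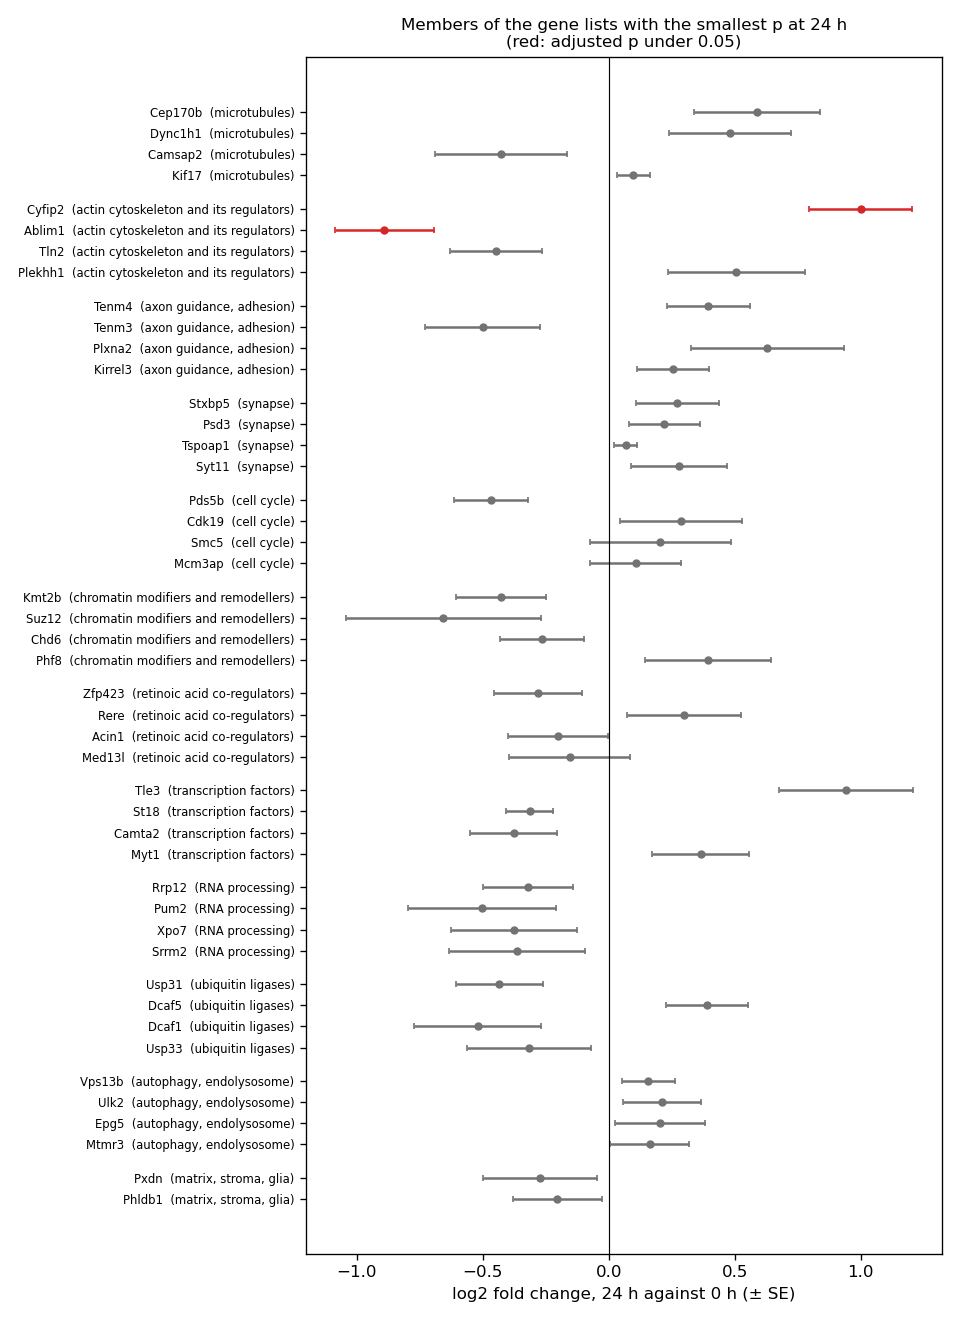
Log2 fold change at 24 h against 0 h (horizontal axis) for the 4 members with the smallest p of 12 of the 13 gene lists (2 members for the last list), with bars for ± 1 SE. Red marks an adjusted p under 0.05, which Cyfip2 (1.00) and Ablim1 (-0.89) reach.

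Fold changes of the 5 times against 0 h were correlated across probes with a median r of 0.50, from 0.28 for 1 and 12 h to 0.66 for 12 and 24 h over 10 pairs of times. All share the 7 control arrays: simulated unchanged groups gave a median of 0.449, and with the controls divided so that no array was shared the median was 0.107. For 12 and 24 h the covariance was 0.0317 against 0.0215 in the simulation, and r with divided controls was 0.222, between 0.0102 and 0.419 over the 35 divisions. Probes are not independent replicates. For the 10 pairs, a share of 0.234 to 0.766 of the simulations gave an r as large as the real one.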

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

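For the 6 probes called at 24 h, the tests of array range, of position and of the 8 arrays above the floor were chosen after the result was seen; the other tests in these paragraphs were written down beforehand.

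Of the measurements far from the rest of their group, 6 were single gene values and 1 was a whole array; 131 groups of values were examined, where chance gives 6.55 such values, and 7 were found. The 3 h replicate 1 array had a median rank correlation of 0.612 with the other arrays, where the nearest array of its group had 0.813. In control replicate 1, Camsap2 was at -0.72 (nearest control 0.27), Tenm3 at 1.02 (nearest 1.56) and Stxbp5 at 0.99 (nearest 0.26), in normalised log2 intensity. Kirrel3 was at -0.56 in control replicate 2 (nearest -0.75), Rrp12 at -0.39 in control replicate 3 (nearest 0.47) and Tspoap1 at -0.55 in 24 h replicate 4 (nearest -0.74). Between late and early times of treatment, Atmin differed by 0.71 and Tenm4 by 0.68 on the log2 scale, each by a test of the difference itself.

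The first pattern is the set of 6 probes called at 24 h. They were further from the control at 12 h than at the mean of 1 and 3 h, though an early part is not excluded. The median of the 12 h value minus that mean, signed by the direction at 24 h, was 0.36 (jackknife SE 0.144). The value was above 0 for 6 of 6 probes. This argues against an effect of the change of medium that was complete by 1 h. It cannot decide on one complete by 3 h, since the 1 h arrays enter the mean. From 3 to 12 h the group mean went from -0.03 to -0.01 for Plekhg1, 0.70 to 0.66 for Mark3 and 4.07 to 4.27 for unnamed probe 439. It went from 0.06 to 0.20 for Cyfip2, 0.92 to 1.47 for Atmin and 0.45 to 0.05 for Ablim1. The 12 h arrays also had a narrower mean range than the early ones, which enters this median too. A median share of 0.833 of the change was left after the correction for position by probe number, with 5 of 6 calls kept. Mark3 went from -0.67 ± 0.16 to -0.51 ± 0.18, a smaller change with a larger SE (limma adjusted p = 0.167). Without the 8 arrays above the floor the median share was 1.37, with 5 calls kept. There Atmin was at 0.83 ± 0.23 with fewer arrays (limma adjusted p = 0.0540). So neither position as taken from the probe number nor these 8 arrays are likely to be the whole cause. With the array range as a covariate a median share of 0.825 was left but only Plekhg1 kept its call. Atmin went from 0.82 ± 0.20 to 0.36 ± 0.20, Ablim1 from -0.89 ± 0.20 to -0.65 ± 0.22, Cyfip2 from 1.00 ± 0.20 to 0.86 ± 0.24 and Mark3 from -0.67 ± 0.16 to -0.53 ± 0.19. Unnamed probe 439 went from 1.59 ± 0.31 to 1.51 ± 0.37, its call ending (limma adjusted p = 0.0619) with a similar change and a larger SE. Range goes with time in this design: the widest 24 h array (1.06) was narrower than the narrowest control (1.23). The narrow range and the treatment therefore cannot be told apart for any of the 6 probes, Plekhg1 included. Retinoic acid, an effect of the lower serum that came after 1 h, and time in culture stay open and untested, since no array had the medium change without retinoic acid.

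The second pattern is the count of probes called late minus early on the values as deposited, 78 against 2 after quantile normalization. Across probes, the late minus early change had a correlation of -0.658 with the mean level (probes are not independent replicates), and of -0.502 without the 8 arrays above the floor. Without these 8 arrays 15 probes were called, but 24 of 100 random sets of 8 arrays from the same groups left as few or fewer (median 30, from 2 to 88). After quantile normalization the correlation with the mean level was -0.0234. A value near 0 follows from making the ranges equal, so it decides nothing about the cause. The correlation on the deposited values leaves open that a narrow range of the late arrays accounts for part of the count. Leaving out the 8 arrays cannot decide it, since these arrays and the smaller number of arrays cannot be told apart. The 24 h arrays that stayed, replicates 1, 4 and 5, were narrow too (interquartile range 0.99, 0.89 and 1.06). No biological explanation was tested for it.

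The third pattern is that arrays numbered 1 deviated from their group means together, with a mean correlation of residuals of 0.323 over 15 pairs. It was 0.289 after the correction for position, which argues against position, as taken from the probe number, as its cause. Among 3 of them that correlated poorly with all arrays (1, 3 and 24 h) it was 0.722, and among the other 3 it was 0.175, from -0.0267 to 0.315, so whether the pattern rests on the 3 poor arrays alone cannot be told apart from a day or batch shared by all 6. The labels give no hybridisation date, and no biological explanation was tested.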

How the results depend on the processing

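Fits without the 8 arrays above the floor, without the 5 arrays of low correlation, with the array range as a covariate, after the position correction, and with weights after that correction were chosen after the data were examined; the others were fixed before. Over 14 settings other than leaving out an array, the 56 named genes and contrasts (51 with dim probes left out) kept direction and side of the threshold in 703 cases, lost the call in 22, gained it in 32 and reversed in 22. Over 38 arrays left out in turn these numbers were 2082, 42, 4 and 0. Most of the 56 were list members without a call to lose, so these totals do not measure how stable the calls were. Over the 14 settings the call ended in 5 for Atmin late minus early, and in 4 for Atmin at 24 h and Ablim1 at 6 h. It ended in 3 for Mark3 and unnamed probe 439, 2 for Cyfip2 and 1 for Ablim1, all at 24 h. For Plekhg1 at 24 h and Tenm4 late minus early it ended in 0. Counts from leaving out dim probes, adding an offset, and a fold minimum of 1.5 stayed within 1.5 times those reported. Replicate numbers did not pair the arrays throughout: of 87 pairs of arrays with the same number 35 had residuals correlated over 0.1 (11 of the 15 pairs numbered 1), and 10 of 38 arrays correlated best with an array of their own number. With the number as a random block, 6 probes passed at 24 h, 1 at 6 h and 2 late minus early (gene lists were not run with it). With it as a fixed block, 8 passed at 24 h, 0 at 6 h, 8 late minus early, 8 late only, and 2 gene lists, both at 1 h: the retinoic acid list upward and the ubiquitin list downward (adjusted p = 0.0199 for both). No value for spot background was available, so what signal over background limits is known only through the floor. The cause was not tested for any of the values below.

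On the values as deposited 1 probe passed at 3 h, 2 at 6 h, 1 at 12 h, 11 at 24 h, 78 late minus early, 17 at any time and 78 late only, with 5 gene lists; Dync1h1 (-0.16), Syt11 (-0.14) and Mcm3ap (-0.077) reversed at 24 h. With median centring 1 passed at 3 h, 2 at 6 h, 12 at 24 h, 65 late minus early, 13 at any time and 65 late only, with 7 gene lists; Dync1h1 (-0.22), Syt11 (-0.21), Mcm3ap (-0.14), Rere (-0.0050) and Dcaf5 (-0.00082) reversed. With array weights 1 passed at 1 h, 15 at 3 h, 2 at 12 h, 21 from 1 to 3 h, 1 from 6 to 12 h, 166 late minus early, 71 at any time, 1 transient and 165 late only. With only the arrays compared 1 passed late minus early and 1 late only. Cyfip2 (log2 0.94) and Mark3 (-0.64) lost their calls at 24 h with changes close to those reported (1.00 and -0.67). With trend and robust variances 0 passed at 6 h, 63 at 24 h (52 at the floor on over 50% of arrays), 80 late minus early (58 at the floor), 62 at any time and 80 late only.

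Without the 8 arrays above the floor 2 passed at 6 h, 11 at 24 h, 4 late minus early and 4 late only, with 1 gene list, and Mtmr3 (-0.088) reversed. Without the 5 arrays of low correlation 1 passed at 3 h, 0 at 6 h, 2 at 12 h, 13 late minus early and 13 late only. With the range covariate 2 passed at 24 h, 6 late minus early, 2 at any time and 6 late only; Camsap2 (0.017), Stxbp5 (-0.051), Mcm3ap (-0.066), Suz12 (0.18), Usp33 (0.0095), Epg5 (-0.052) and Pxdn (0.0037) reversed. After the position correction 1 passed at 3 h, 2 at 12 h, 10 late minus early and 10 late only, with 1 gene list, and Kif17 (-0.077) and Mcm3ap (-0.031) reversed. With weights after it 3 passed at 1 h, 6 at 3 h, 4 at 6 h, 6 at 12 h, 44 at 24 h, 10 from 1 to 3 h, 5 from 6 to 12 h, 2 from 12 to 24 h, 89 late minus early, 81 at any time, 2 transient and 87 late only; Kif17 (-0.030), Psd3 (-0.053), Mcm3ap (-0.10) and Acin1 (0.0000997) reversed.

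Calls gained at 24 h were Pds5b and Usp31 on the values as deposited and with median centring, Tle3 with dim probes left out and with the fixed block, Cep170b and St18 with array weights, Pds5b, St18 and Tle3 with trend and robust variances, Psd3 and Tle3 without the 8 arrays, Usp31 after the position correction, and 18 list members with weights after it.

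Leaving out single arrays gave 0 to 0 probes at 1 h, 0 to 1 at 3 h (1 without 3 h replicate 5), 0 to 1 at 6 h, 0 to 2 at 12 h (2 without 12 h replicate 5), 4 to 10 at 24 h (10 without control replicate 1), 0 to 1 from 6 to 12 h (1 without 12 h replicate 5), 1 to 12 late minus early and late only, 4 to 8 at any time, and 0 for the other steps and for transient and continued probes. Gene lists gave 0 to 1 (the ubiquitin list at 1 h, without any of 10 arrays), and the similarity of time points had a median r from 0.383 to 0.618. Late minus early gave 12 without 24 h replicate 1, 6 without 3 h replicate 5, 5 without 12 h replicate 5, 4 without 1 h replicate 1 or 5, and 1 without 1 h, 3 h or 24 h replicates 2 or 3. Ablim1 lost its call at 6 h without control replicates 1, 3, 4, 5 or 6, 1 h replicates 2 or 3, 3 h replicate 3, 6 h replicates 2, 3, 4, 5 or 7, 12 h replicates 3, 4, 5 or 6, or 24 h replicates 2, 3 or 6 (adjusted p from 0.0237 to 0.182 over all 38). At 24 h Atmin lost its call without control replicates 2, 4, 5, 6 or 7 or 24 h replicates 2, 3 or 5 (0.00887 to 0.0947), and Mark3 without control replicates 4, 5, 6 or 7 or 24 h replicates 2, 4 or 5 (0.0102 to 0.0941). Late minus early, Atmin lost its call without 1 h replicates 2, 3 or 4, or 3 h or 24 h replicates 2 or 3 (0.000971 to 0.0803). At 24 h Tle3 passed without control replicate 1, 6 h replicate 1 or 24 h replicate 6, and St18 without control replicate 1.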

Other observations

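Abundant cytoskeletal and housekeeping genes and a neurofilament, chosen after their values were seen, did not pass at 24 h in the fit described. Of 10 housekeeping and cytoskeletal genes looked for 4 were on the array: Actg1 was at -0.80 ± 0.32 (log2 ± SE), Gapdh at -0.52 ± 0.29, Actb at -0.51 ± 0.43 and Tubb5 at -0.29 ± 0.35. Of 17 neuronal markers only the heavy neurofilament Nefh was measured, at -0.31 ± 0.16. On the values as deposited these 5 were at -1.24, -0.93, -1.01, -1.07 and -0.81, and after median centring at -1.31, -0.996, -1.08, -1.13 and -0.88. The median of all probes was at 0.09 and 0.02. None of the 5 passed under either scaling. They are bright probes, at percentile 99.3 to 99.8 of the mean level and 92.5 for Nefh. As deposited, brighter probes went lower from early to late times (correlation -0.658 with the mean level), so the median of all probes is no like comparison. Actg1 passed without control replicate 1, and Actg1 and Nefh passed with weights after the position correction.

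Position on the array explained 29.9% of the variance of the normalised values around their probe means, where 5.91% is expected and the highest of 100 shuffles gave 6.96%. The first principal component held 25.2% of the variance.

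Random splits of the arrays into groups of the same sizes, 100 for each result with the real one included, were counted as planned. The limit set in advance was under 5 in 100 splits, not adjusted over the results. At 24 h it was met, since only the real split reached the count of 6 (highest other 3). For late-only probes only the real split reached 2 (highest other 0), but these are the same Tenm4 and Atmin as late minus early. With 100 splits for each of many results, meeting the limit does not exclude chance. Splits also mix arrays of different range, so an effect of range could meet the limit as well. The limit was also met for late minus early, where 2 splits reached 2, and for any time, where 3 splits reached 6, but other splits gave more than the real one there (highest other 4 and 10). The limit was not met at 6 h, where 5 splits reached 1 (highest other 13). Nor was it met for the similarity of the time points, where 40 splits reached a median r of 0.50 (highest other 0.819). Chance stays open for these too. For counts of 0 every one of the 100 splits was as large: 1 h (highest other 1), 3 h (highest other 1), 12 h (6), 1 to 3 h (0), 3 to 6 h (3), 6 to 12 h (13), 12 to 24 h (11), transient (0) and continued probes (0), and gene lists (2). Splits that called far more probes than the real one, at 6 h, at 12 h, from 6 to 12 h and from 12 to 24 h, may reflect a structure of the samples, which was not tested.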
